A study of Mus musculus with 3 samples.

How the data were processed

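The series holds 3 chromatin immunoprecipitation sequencing (ChIP-seq) samples of a single group. RAW264.7 is an established mouse macrophage line. The cells carried a doxycycline-inducible construct encoding NUR77, an orphan nuclear receptor and transcription factor of the NR4A family, fused to an HA epitope tag. Per the labels, each replicate came from 6 dishes treated with 1 µg/mL doxycycline for 18 hours, cross-linked with both a protein cross-linker and formaldehyde, and precipitated with an antibody against the HA tag. No sample without doxycycline, without the tag or with a control antibody was analysed here. The series' design text says that input reads of other studies were re-used as controls; they were not analysed here.

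For each replicate the authors deposited a list of called peaks with a position and a peak score. The coordinates are of mouse genome build mm9, per the submitters' processing notes. The names of the peaks are of the form that MACS, a model-based peak caller, gives. The caller's version, its threshold, the aligner and the way the control reads entered are not given in the sources used here. The scores had 3 decimals and did not exceed 1000, and their scale is not stated, so a score was used only to rank peaks within its own list. In replicate 2, 549 peaks shared the score 958.844, in replicate 3, 7 peaks shared 982.013, and in replicate 1, 6 peaks were at 1000, so peaks within such a tie were not resolved from each other. The ties of replicates 2 and 3 are not the top of their lists, as 609 and 8 peaks scored at or above them. Peak widths were multiples of 50 bp for 99.3%, 96.5% and 99.7% of the peaks of replicates 1, 2 and 3, which sets the precision of peak borders. The peak numbers in the names had gaps. Of the numbers up to the highest, 39.1%, 19.7% and 38.8% were absent from the lists of replicates 1, 2 and 3, so the lists analysed hold only part of the peaks that were numbered.

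A series-wide table deposited by the authors gives the intervals over which at least 2 of the 3 replicates had a peak, with the names of those replicates and no score. Neighbouring stretches covered by different replicates are separate rows in it. The table was rebuilt from the 3 lists as a check. All 19164 intervals had the same borders. The replicate names matched for 13753 intervals as written and for 19164 when the table's names for replicates 2 and 3 were exchanged, so replicate numbers here follow the sample titles of the lists. Touching intervals were joined, which gave 9800 regions, and these were used for positions and clustering. Peaks had been called in each replicate separately, so agreement could be measured between lists.

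Peaks of different lists were called shared if they overlapped by at least 1 bp. Overlap was tested against 1000 random placements of 1 list's peaks within their own chromosomes, one-sided, with the mm9 chromosome lengths of GenomeInfoDb 1.38.1. The smallest p that 1000 placements can give is 0.001. Random placement ignores gene density, open chromatin and unmappable sequence, so it shows agreement beyond random positions and not more. Overlapping peaks of the 3 lists were also merged into regions and counted by the replicates they held. The scores of shared and unshared peaks were compared by the probability that a shared peak scores higher (area under the curve), with no p-value, since peaks are not replicates. Peak density per chromosome was divided by the density over all nuclear chromosomes. Clustering was measured as the share of regions whose centre had another centre within 50 kb divided by 4, or about 13 kb. Shares carry 95% Wilson intervals, which cover counting error only.

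The text names the 25 regions with peaks in all 3 replicates that had the lowest mean rank by score over the 3 lists. This rule, the tests and the alternatives listed next were fixed before the data were examined. The alternatives were an overlap of at least 50% of both peaks, centres within 100 bp, the higher-scored 50% of each list, an equal 6777 best-scored peaks from each list, the numbered chromosomes and X only, neighbour distances of 5 and 50 kb, regions of all 3 replicates, and leaving out each replicate. The plan also held 14 gene lists, a breakdown by genomic feature and 12 binding motifs. These need an mm9 gene annotation or genome sequence, which was not used here. The gene table at hand is of GRCm38, and coordinates were not converted between builds, so regions are given by position and no gene is assigned to them. Read counts are not part of the peak lists, so the sequencing depth of each sample is unknown here. The computations were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on simulated data: of 4000 peaks planted on replicate 1 with shifted borders, 100% were found, and 0.251% of randomly placed peaks were called overlapping. The shifts were smaller than the narrowest replicate 1 peak, so each planted peak had to be found. The 100% therefore checks the code only.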

Results

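NUR77 binding across the genome was profiled by ChIP-seq against the HA tag in RAW264.7 macrophages with induced HA-NUR77, in 1 group of 3 replicates. The peak lists held 6777 peaks for replicate 1, 37307 for replicate 2 and 8862 for replicate 3, a mean of 17649 ± 17057 (SD, n = 3). Replicate 2 had 5.50 times as many peaks as replicate 1 and 4.21 times as many as replicate 3. The median peak width was 350 bp in replicates 1 and 3 and 500 bp in replicate 2. Peaks covered 2.33 Mb in replicate 1, 18.4 Mb in replicate 2 and 3.22 Mb in replicate 3. The group has no counterpart without induction, so the comparisons are between replicates and between parts of the genome. The labels give each replicate its own dishes and do not say whether they were prepared on separate days.

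The replicates were compared first, since the study kept the sites seen in at least 2 of them. The peaks called in replicates 1 and 3 mostly overlapped peaks called in replicate 2. Of the replicate 1 peaks, 91.8% (95% Wilson interval 91.1 to 92.4) overlapped a peak of replicate 2, and of the replicate 3 peaks, 91.2% (90.6 to 91.8) did. Replicate 1 shared 71.6% (70.5 to 72.7) of its peaks with replicate 3, and replicate 3 shared 54.8% (53.7 to 55.8) of its peaks with replicate 1. Of the longer replicate 2 list, 16.7% (16.3 to 17.1) of peaks overlapped replicate 1 and 21.7% (21.3 to 22.1) overlapped replicate 3. Random placement gave means between 0.193% and 1.26% for the same pairs, and the highest single placement reached 1.76%, for replicate 1 peaks in replicate 2. In each of the 6 ordered pairs the observed share exceeded all 1000 random placements (one-sided permutation test, p = 0.001, the smallest that the placements can give), and it was 71.8-fold or more above the mean of the placements. With a reciprocal overlap of 50%, the shares found in replicate 2 were 61.3% for replicate 1 and 69.1% for replicate 3. Replicate 1 then shared more peaks with replicate 3 (65.7%) than with replicate 2. With centres within 100 bp this order was reversed, as replicate 1 shared 77.4% of its peaks with replicate 2 and 60.4% with replicate 3. With each list limited to its 6777 best-scored peaks, the pairs shared 59.0% to 64.4% of their peaks. Centres of overlapping peaks lay a median of 41 to 46 bp apart.

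Higher-scored peaks were more often shared. With each list divided into 10 equal groups by score, the share of peaks that overlapped both other replicates was 34.4% in the lowest-scored and 86.4% in the highest-scored group of replicate 1, 0.509% and 69.1% in replicate 2, and 19.2% and 84.0% in replicate 3. In replicate 1 it was highest, at 89.4%, in the group next to the top. From the best-scored 1000 peaks to the best 100 the share did not rise further in any replicate. In the best-scored 100 peaks of replicates 1, 2 and 3 it was 80%, 88% and 82%. In the best 1000 it was 87.5%, 89.4% and 84.3%, so in replicate 2 it still rose within the highest-scored group (69.1%). The best 100 of replicate 2 cut through its tie at 958.844. Overlap with any other replicate rose from 2.44% to 86.2% in replicate 2. It ranged only from 85.7% to 97.9% in replicate 1 and from 84.2% to 96.8% in replicate 3, where replicate 2 overlapped 91.8% and 91.2% of all peaks. A shared peak scored higher than an unshared one with a probability of 0.648 in replicate 1, 0.870 in replicate 2 and 0.650 in replicate 3, a mean of 0.723 ± 0.128 (SD, n = 3), above even odds in 3 of 3 replicates. It depended on the partner lists, which define sharing, so the values of the 3 replicates are not independent. Without replicate 2 it was 0.760 in replicate 1 and 0.771 in replicate 3, while it was 0.588 in replicate 1 without replicate 3 and 0.581 in replicate 3 without replicate 1. In replicate 2 it was 0.876 without replicate 1 and 0.883 without replicate 3. In replicate 2 the median score was 237 for shared and 59.0 for unshared peaks. Across overlapping peaks, the scores of 2 replicates ranked alike, with a Spearman rho of 0.69 for replicates 1 and 2, 0.79 for 1 and 3, and 0.71 for 2 and 3. These are correlations across peaks, which are not independent replicates, and the score is the authors' own value for each peak.

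**Figure D1:**
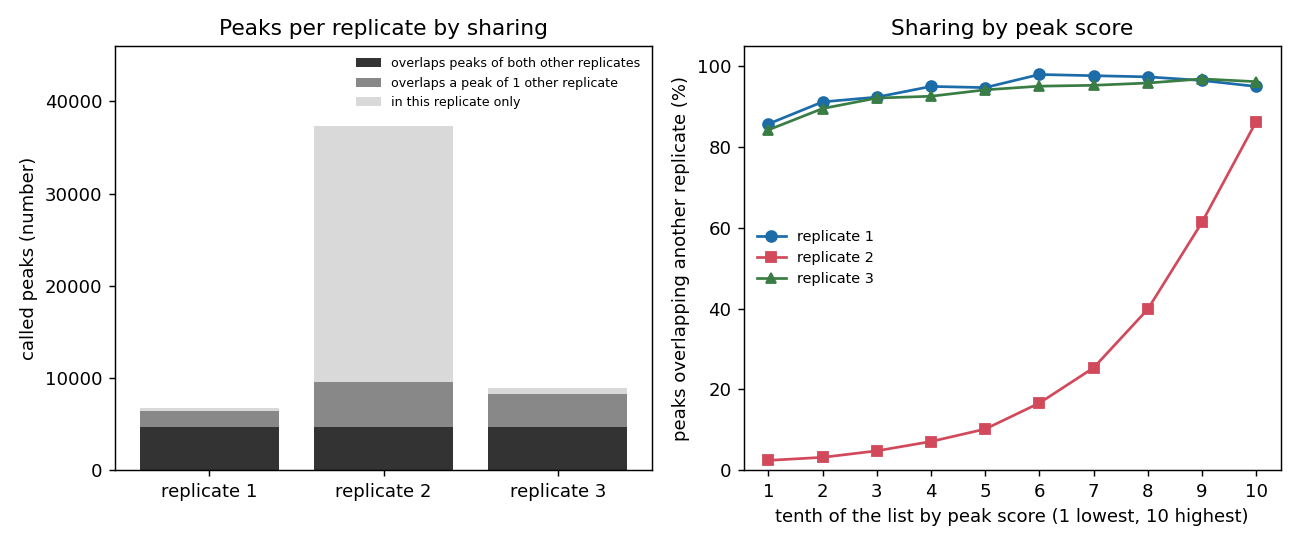
Left, number of called peaks in each of the 3 replicates, split into peaks that overlap both other replicates, 1 other replicate or neither; right, percentage of peaks that overlap any other replicate (y axis) in 10 equal groups of each list ordered by peak score (x axis). Replicate 2 rises from 2.44% to 86.2%, while the lowest values of replicates 1 and 3 are 85.7% and 84.2%.

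Merging the 3 lists gave 38463 regions, of which 9755 held peaks of at least 2 replicates and 4723 held peaks of all 3. Replicate 2 alone accounted for 27717 regions, replicate 1 alone for 385 and replicate 3 alone for 606. Replicates 2 and 3 without replicate 1 shared 3364 regions, replicates 1 and 2 without replicate 3 shared 1499, and replicates 1 and 3 without replicate 2 shared 169. Of the regions with at least 2 replicates, 98.3% included replicate 2. Without replicate 2 the number of regions common to the remaining replicates was 4854, without replicate 3 it was 6220, and without replicate 1 it was 8085. The authors' deposited table divides the overlaps of at least 2 replicates into 19164 intervals. Joined where they touch, they form 9800 regions with a median width of 350 bp that cover 3.60 Mb, and 4681 of these (47.8%) included a stretch covered by all 3 replicates. In the table, intervals named for replicates 1 and 3 number 5089 and those named for replicates 1 and 2 number 322. Rebuilt from the lists, these counts were exchanged, with 5089 for replicates 1 and 2 and 322 for replicates 1 and 3.

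The 25 best-ranked regions of all 3 replicates lay on 12 chromosomes, with 5 on chromosome 2, 4 on chromosome 5, 3 on chromosome 3, 2 each on chromosomes 1, 9, 11 and Y, and 1 each on chromosomes 4, 8, 10, 18 and the mitochondrial genome. They were 502 to 1350 bp wide, with a median of 602 bp against 450 bp for the 4681 regions of all 3 replicates. The first by this rule was on chromosome 11 at positions 68886934 to 68887606 (mm9), with ranks of 77 in replicate 1, 5.5 in replicate 2 and 173 in replicate 3. On chromosome 5, the region at 108675276 to 108675953 ranked 11 in replicate 1 and 1 in replicate 3, and the region at 17382476 to 17383153 ranked 14 and 15. On chromosome 4, the region at 15921487 to 15922066 ranked 10 and 11. On chromosome 9, the region at 75044148 to 75044749 ranked 15 and 10. On chromosome 2, the region at 129729047 to 129729648 ranked 16 and 12, and a pair of named regions lay close together, at 46215699 to 46216296 and at 46226449 to 46227046. On chromosome 18, the region at 66637726 to 66638325 ranked 29 and 9. In replicate 2, 23 of the 25 regions shared the tied score of 958.844, so they share rank 335 there and their order rests on replicates 1 and 3. The first region, with a replicate 2 score of 996.663, and the region on chromosome 3 at 103662118 to 103662619, with 998.138 and ranks of 210 in replicate 1 and 170 in replicate 3, owe their places to scores above that tie. In replicates 1 and 3 both ranked behind the other 23 regions.

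Of the other named regions, those on chromosomes 1, 3, 8 and 10 ranked between 18 and 210 in replicate 1 and between 14 and 170 in replicate 3. The region on chromosome 1 at 182756624 to 182757273 ranked 39 and 14, and that at 107644824 to 107645423 ranked 28 and 17. On chromosome 3 the regions at 78956868 to 78957519 and at 106592820 to 106593369 ranked 23 and 18 in replicate 1. The region on chromosome 8 at 109793160 to 109793675 ranked 22 and 28, and the region on chromosome 10 at 16754417 to 16755142 ranked 41 and 19. The remaining named regions lay on chromosome 2 at 136762167 to 136762898 and at 139667097 to 139667646, on chromosome 5 at 5420126 to 5420725 and at 73154076 to 73154703, on chromosome 9 at 96293548 to 96294049 and on chromosome 11 at 70002984 to 70003636. They ranked between 19 and 38 in replicate 1 and between 18 and 43 in replicate 3.

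The sole peak on the mitochondrial genome was called at positions 5702 to 6451 in all 3 replicates, with scores of 1000, 958.844 and 982.013. On chromosome Y, named regions lay at 2789130 to 2789892 and at 2876030 to 2877379. Between 2777380 and 2897979 on this chromosome, a stretch picked after its values were seen, 9 peaks were called in replicate 1, 17 in replicate 2 and 6 in replicate 3. Their median scores were 867, 595 and 982, against 44.7, 78.0 and 50.4 for the whole lists. They included 4 of the 6 peaks that scored above 900 in replicate 1, 7 of the 707 in replicate 2 and 4 of the 11 in replicate 3. No control sample or input was analysed here. Whether the high scores on chromosome Y and the mitochondrial genome reflect NUR77 binding was therefore not tested. The same holds for all other peaks and regions given here.

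**Figure D2:**
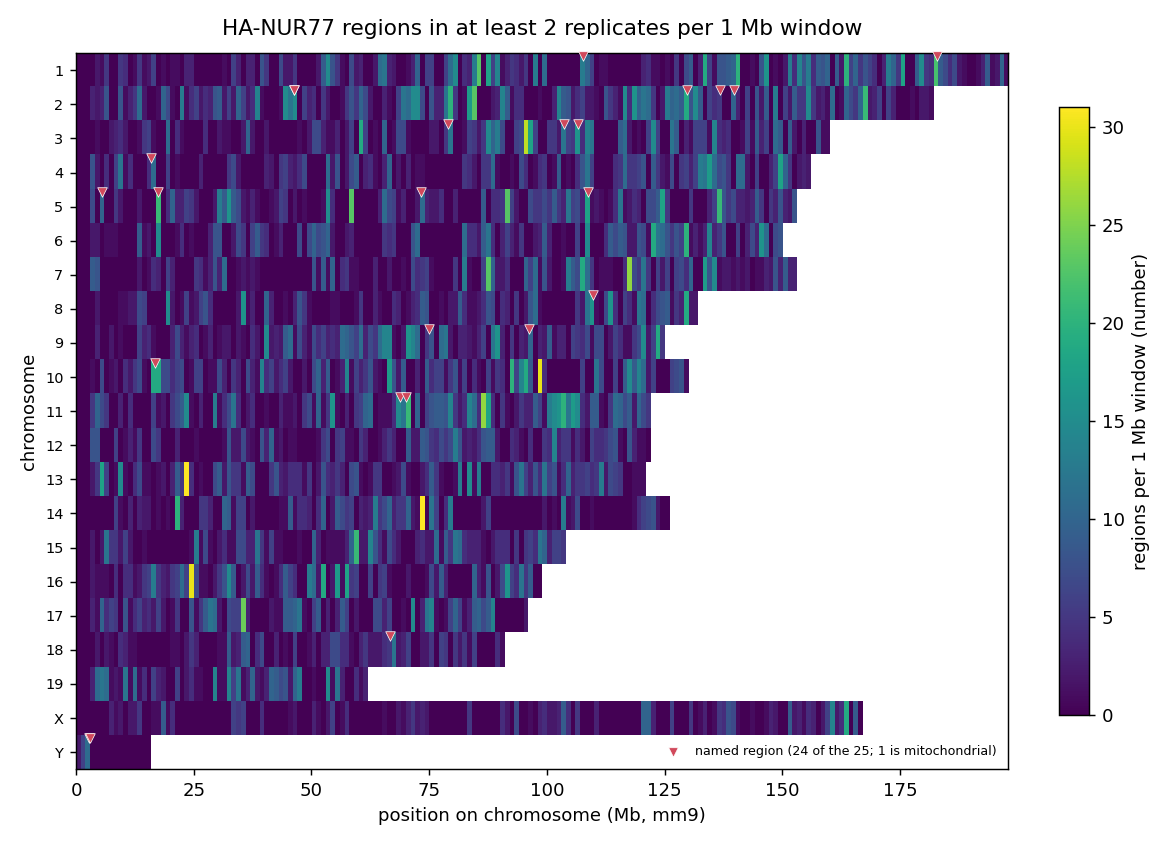
Number of HA-NUR77 regions found in at least 2 replicates in each 1 Mb window (colour) along the mm9 chromosomes (x axis, Mb), with triangles at 24 of the 25 best-ranked regions; the remaining one is mitochondrial. The densest windows, with 31 regions each, are on chromosomes 13 and 14.

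Peaks were spread unevenly over the chromosomes, and the same chromosomes were dense or sparse in the 3 replicates. Chromosome 11 had the highest density, 1.49 ± 0.020 times that of all nuclear chromosomes (SD, n = 3), and chromosome 2 followed with 1.33 ± 0.067. Chromosome 18 was the sparsest autosome, with 0.65 ± 0.082, and chromosome 14 had 0.771 ± 0.020. Of the 19 autosomes, 10 were above 1 and 8 below 1 in all 3 replicates. Chromosome X had 0.468 ± 0.028 and lay below all 19 autosomes in each replicate, with 0.451 in replicate 1, 0.452 in replicate 2 and 0.500 in replicate 3. The sparsest autosome had 0.609, 0.744 and 0.597 in the same replicates. The gap between chromosome X and the sparsest autosome exceeded the SD between replicates, which does not measure the spread between chromosomes. Chromosome Y had 0.250 ± 0.092, over a length of 15.9 Mb of which no peak lay beyond position 2897979, so this value depends on the length counted. Among regions with at least 2 replicates, chromosome 11 held 660 (5.42 per Mb), chromosome 2 held 910 (5.01 per Mb) and chromosome X held 294 (1.76 per Mb). Chromosomes are not replicates, so no test was applied between them.

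**Figure D3:**
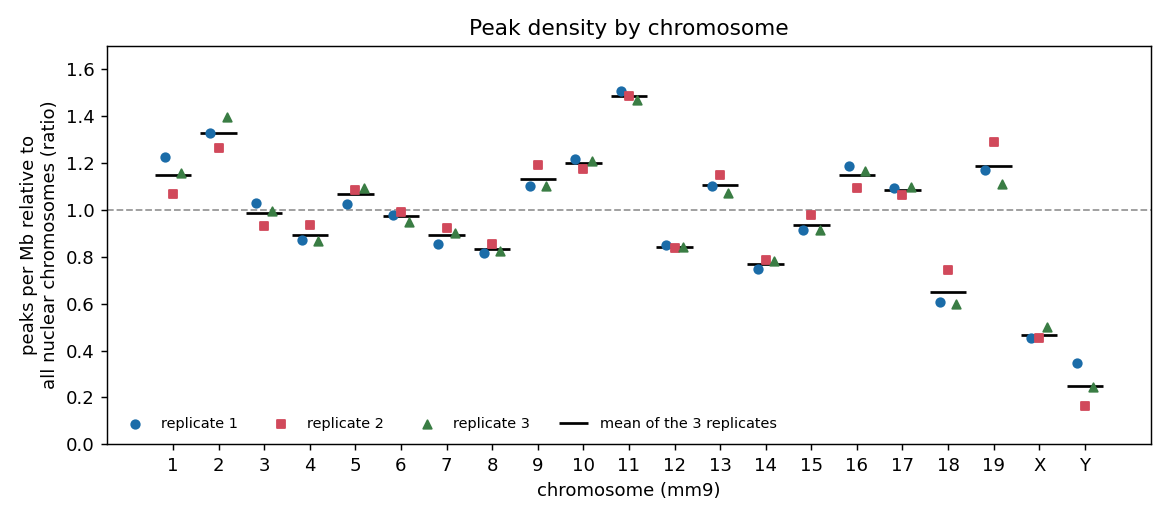
Peaks per Mb of each mm9 chromosome divided by the peaks per Mb of all nuclear chromosomes (y axis, ratio) for the 3 replicates (symbols) and their mean (black lines). Chromosome 11 has the highest mean (1.49) and chromosome X (0.468) lies below all 19 autosomes in each replicate.

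The regions seen in at least 2 replicates lay closer together than random positions. Of the 9800 regions, 36.1% had another region within about 13 kb between centres, against a mean of 9.28% and a highest value of 10.7% over 1000 random placements (one-sided permutation test, p = 0.001, the smallest that the placements can give). When each region was placed at random within its own 1 Mb window, a comparison chosen after seeing the data, the mean was 18.3%. Joined at the same distance, the regions formed 1473 groups of 2 or more that held 3535 regions, and 44 of these groups held 5 or more. The largest groups, named after their values were seen, were on chromosome 13 at 23789320 to 23845180 with 13 regions, on chromosome 8 at 19932078 to 19970459 with 11, and on chromosome 9 at 89091298 to 89116047 and chromosome 1 at 87485274 to 87521723 with 10 each. All 3 replicates were present in 6 of the 13 regions on chromosome 13 in 4 of the 11 on chromosome 8, and in 2 of the 10 in each of the groups on chromosomes 9 and 1. The clustered share was 22.3% without replicate 2, whose random mean was 4.77%.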

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

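The random placement within 1 Mb windows and the density relative to the autosomes were chosen after seeing the data. The overlap between replicates, the clustering of regions and the higher scores of shared peaks kept their direction under each alternative run on them, and both random-placement tests stayed at p = 0.001 (permutation). The mean share over the pairs of replicates was 58.0%, and ranged from 45.7% with a reciprocal overlap of 50% to 63.2% without replicate 2. The higher-scored 50% of each list gave a mean of 8825 peaks, 4750 regions in at least 2 replicates, 2557 in all 3, and relative densities of 0.391 for chromosome X and 1.59 for chromosome 11. The lower counts follow from the shorter lists, and for the densities the cause was not tested. With 6777 peaks from each list, 5922 regions were in at least 2 replicates, again from shorter lists. Leaving out each replicate gave 4854 to 8085 such regions, lowest without replicate 2. Relative to the autosomes alone chromosome 11 had 1.43, since X and Y, with fewer peaks per Mb of listed length, no longer enter the reference. No paired analysis was possible because there is 1 group. The breakdown by genomic feature, the gene lists and the motifs were not run, nor their alternatives, as they need an mm9 annotation or genome. The depth of each sample is unknown, so a region without a peak in a replicate is not shown to be unbound there.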

Other observations

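The densest 1 Mb windows, picked after their values were seen, were on chromosome 14 at 73000001 to 74000000 and on chromosome 13 at 23000001 to 24000000, with 31 regions each against a mean of 3.68 per window. All 3 replicates were present in 19 of the regions in the chromosome 14 window and in 11 of those in the chromosome 13 window. Chromosome 16 at 24000001 to 25000000 and chromosome 10 at 98000001 to 99000000 held 30 regions each, and chromosome 3 at 95000001 to 96000000 held 28. No region was found in 918 of the 2665 windows, which span the full mm9 chromosome lengths. Windows of gaps or unmappable sequence were not set apart, so this count and the mean of 3.68 include any such windows. In the window on chromosome 1 at 85000001 to 86000000, the lists differed less in length, with 23 peaks in replicate 1, 28 in replicate 2 and 30 in replicate 3. The ratio of replicate 2 to replicate 1 was 1.22 there, against 2.33 to 4.14 in the other 9 of the 10 densest windows and 5.50 over the whole lists. The windows were picked for regions seen in at least 2 replicates, which favours peaks of the shorter lists. That choice by itself lowers the ratio below 5.50.

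Each list held some strong peaks that no other list had. Of the best-scored 1000 peaks, 47 in replicate 1, 44 in replicate 2 and 36 in replicate 3 overlapped no other list. The highest-scored peaks of replicate 2 alone, picked by their values, lay on chromosome 10 at 117488979 to 117489478 with a score of 998.525 and on chromosome 12 at 100880767 to 100881366 with a score of 995.113. Of the 27717 replicate 2 peaks that overlapped no other list, 379 (1.37%) scored above 381.762, the median of replicate 2 peaks that overlapped both other lists.

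The 4 tests reported next were fixed before their values were computed, but after related values had been seen, among them the sharing by score and the X density of each replicate. Replicate 2 has several times as many peaks as replicates 1 and 3. Background calls spread evenly within 1 Mb windows are argued against as the source of all these peaks. Of the unshared replicate 2 peaks, 25.3% lay within about 13 kb of a region seen in at least 2 replicates. This was 1.79 times the 14.1% of random positions in the same 1 Mb windows. Such positions ignore open chromatin and unmappable sequence, so background that gathers near these regions was not tested. With lists of equal length, pairs with replicate 2 shared a mean of 61.4% of peaks and the pair without it 64.4%, a gap of 3.04 percentage points, which is consistent with a list that holds the same strong regions plus weaker ones. The mean with replicate 2 combined 59.0% for replicates 1 and 2 and 63.7% for replicates 2 and 3. Replicates 1 and 2 alone lay more than 5 percentage points, the limit set for the mean, below the pair without replicate 2. Of the best 6777 replicate 2 peaks, 1635 overlapped neither of the shorter lists. The highest peak numbers in the names, 11123, 46455 and 14478 in replicates 1, 2 and 3, already differed. Fewer numbers were absent in replicate 2 (19.7%) than in replicates 1 (39.1%) and 3 (38.8%), which adds to its longer list. Depth, precipitation efficiency and threshold stay open as sources of the longer list, and no biological explanation was tested, since the labels give the 3 replicates the same treatment.

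Chromosome X had 0.468 times the peak density of all nuclear chromosomes. Windows wholly without callable sequence are argued against as the whole cause. Among 1 Mb windows with at least 1 replicate 2 peak, chromosome X had 0.604 times the autosomal mean (95% bootstrap interval over windows 0.514 to 0.701). A peak was held by 59.9% of the X windows against 83.4% on the autosomes. Callable length inside windows was not measured, so gaps or unmappable sequence within occupied windows stay open. RAW264.7 derives from a male mouse, and a single X copy may lower the signal and push X peaks below the threshold, which stays open because the values point both ways. In replicate 2 the X density relative to the autosomes was 0.517 in the lower-scored 50% of peaks and 0.350 in the higher-scored 50%, a ratio of 1.48 (95% interval 1.30 to 1.67) that restates the lower X density of higher-scored peaks and would also arise from fewer strong regions on X or more background among weak peaks. Against it, the X density relative to the autosomes was no higher in the longest list, with 0.434 in replicate 1, 0.433 in replicate 2 and 0.481 in replicate 3. No explanation that needs a comparison of groups was tested, as the design has 1 group.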
